A study of Mus musculus with 2 samples.

How the data were processed

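H3K4me2, a histone mark found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the forebrain of B6NCrl mouse embryos at embryonic day 12.5. The labels give 1 group with 2 biological replicates, each a pool of embryos of both sexes, 120 embryos for replicate 1 and 68 for replicate 2. The files are peak lists on mm10: 1 list per replicate, 1 list from the pooled reads of both replicates and 1 list of replicated peaks. Per the file headers, each replicate's list was made from its own filtered alignments and a control alignment, the pooled list from the alignments and controls of both replicates, and the replicated list from the other 3 lists. The control alignments, alignments and signal tracks that these records name were not analysed here. The aligner, the peak caller, their versions and the threshold are not given in the sources used here.

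The authors' fold enrichment of each peak over control, a linear ratio, was used as deposited. The deposited lists also give each peak a −log10 p-value and a −log10 q-value. The smallest −log10 p was 2.00 in the list of replicate 1 and 2.04 in that of replicate 2. The files hold no read counts, so the depth of the libraries is unknown and no interval for counting reads was computed. Intervals of shares of peaks or genes are Wilson intervals at a confidence level of 95%; they treat peaks or genes as independent, which neighbouring ones are not. Fold enrichments were compared by rank and as log2 ratios between the replicates, and as medians between groups of peaks or genes within a list; they are not amounts of the mark.

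Genes, transcripts and exons came from GENCODE release M21 and base composition from the matching mouse sequence. Analyses used the 19 autosomes, X and Y. Where more than 1 protein-coding gene carried a symbol, the longest was kept and the others (27) were dropped, which left 21911 protein-coding genes. A gene had a TSS peak when a peak reached within 1 kb of any of its annotated transcription start sites (TSSs). TSS coverage was the number of bases under peaks within 10 kb either side of the outermost annotated 5′ end. Distal peaks lay over 2.5 kb from every annotated TSS and were counted within 100 kb of the 5′ end. A domain was the run of peaks over a TSS of the gene, joined over gaps of up to 500 bp. A TSS was CpG-rich when observed over expected CpG was at least 0.6 within 500 bp either side, taking the highest value among the gene's TSSs.

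The 20 gene lists, the genes to be named, the tests and most alternatives were fixed before the data were examined. Named genes were, for each list, the 3 most covered members and up to 3 in alphabetical order without a TSS peak, or the least covered where all had one. The rule also took the 20 protein-coding genes with the widest domains, a fixed set of landmark genes, the 10 replicated peaks with the highest fold enrichment and the 10 genes nearest to most distal peaks. The listed erythroid gene Ahsp was not found as a protein-coding symbol, which left 18 of 19 genes in that list.

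Shares of peaks overlapped by another list, by at least 1 bp, were set against 1000 circular shifts of that list along each chromosome (100 shifts for reciprocal overlap of 50%). The share of genes with a TSS peak in a list was set against all other protein-coding genes with Fisher's exact test, two-sided. Mean coverage and mean numbers of distal peaks were set against 100000 random lists of the same size, two-sided, for which the smallest p is 1e-05. Sets of factors were compared by two-sided permutation tests of the difference of means, with 95% bootstrap intervals from 10000 resamples. Values were adjusted by Benjamini-Hochberg over the 20 lists of each measure, and a list was called at an adjusted p under 0.05. These tests take genes as the units and hold for this peak set; with 1 group and 2 replicates they do not measure variation between embryos.

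On simulated data for 21911 genes, 98% of changed lists were called with the right direction for TSS peaks, 100% for coverage and 79.5% for distal peaks, and 1.5%, 2% and 0% of unchanged lists were called. The simulated changes were large: 100% or 25% against 67% for TSS peaks, and 3 times the mean or a small fraction of it for the others. Simulated lists held 25 genes drawn at random with independent values. These rates therefore do not hold for smaller changes or for lists of neighbouring genes. In lists simulated to depend on a covariate alone, matching lowered the share called from 100% to 5%. The simulated covariate took 5 levels and the matching used those same levels. It therefore cannot show that matching in 5 bins removes the effect of CpG, which varies within a bin. For 20000 simulated peaks of which 70% were kept in a second list, 69.9% were found to overlap. Alternatives were a stricter fold enrichment (the list median or higher), the pooled list, each replicate's own list, other windows and distances, and random lists matched in 5 bins on CpG at the 5′ end or on neighbouring genes. CpG was matched at the outermost 5′ end only, while a TSS peak could lie at any TSS of a gene. Chosen after seeing the data were the replicated peaks that a peak of each replicate overlapped by at least 50% of either, matching on the number of CpG sites within 10 kb, keeping for distal peaks 1 gene of each list per 100 kb, and leaving out TSS peaks that also covered a TSS of another protein-coding gene. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1, with matplotlib 3.10.9 for figures.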

Results

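H3K4me2 was profiled in the mouse forebrain at embryonic day 12.5, when the pallium (the future cortex), the subpallium (the future basal ganglia) and the diencephalon hold dividing progenitors and newly formed neurons. The 2 biological replicates were pools of 120 and 68 embryos and form 1 group, so no group comparison was possible. The list of replicate 1 held 53010 peaks over 52.3 Mb and that of replicate 2 held 52527 peaks over 50.3 Mb (52769 ± 342 peaks, mean ± SD, n = 2). The pooled list held 55960 peaks, and the replicated list, used below unless another is named, held 36496 peaks over 54.0 Mb, 1.98% of the assembled chromosomes. Its median peak width was 1082 bp and its median fold enrichment 10.5. The sequencing depth is unknown.

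The peaks with the highest fold enrichment lay at promoters. The highest replicated peak, at Egr1, a transcription factor gene of the immediate early response, spanned 34858974 to 34863297 on chromosome 18 with a fold enrichment of 70.4 (58.8 ± 6.31 in the lists of both replicates, n = 2). It was followed by peaks at Usp43 (69.7), Sptb (64.99), Map3k10 (63.1) and Kcnq4 (62.9), and all 10 of the highest peaks overlapped a TSS window. How far the replicates shared their peaks was the first comparison. Peaks of replicate 2 overlapped 72.4% of the peaks of replicate 1 (38344 of 52997), and peaks of replicate 1 overlapped 76.1% of those of replicate 2 (39942 of 52514). After circular shifts the mean shares were 3.64% and 3.71%, and no shift reached the observed value (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Over 35400 pairs of peaks that overlapped each other best, the fold enrichments ranked alike, with a Spearman rho of 0.934 across peaks, which are not independent replicates. Shared peaks of replicate 1 had a median fold enrichment of 9.74 and those found in replicate 1 alone 3.04. In decile 1 of 10 of replicate 1 peaks by fold enrichment 28.1% were shared, and in decile 10 100%. With reciprocal overlap of 50% the shares were 57.4% and 57.9%.

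Every peak of the replicated list was also a row of the pooled list. Of 55946 pooled peaks on assembled chromosomes, 65.2% were in the replicated list, 99.9% of those at or above the median fold enrichment and 30.5% of those below it. All 34297 pooled peaks that a peak of each replicate overlapped by at least 50% of either were kept. A further 2188 replicated peaks (5.997%) lacked that overlap, with a median fold enrichment of 3.20 against 12.7 for the rest, and 2136 of them had it in 1 replicate.

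The next comparison was where the replicated peaks lay. Of the replicated peaks 52.0% (18955 of 36485) reached within 1 kb of an annotated TSS, against a mean of 9.91% for shifted TSS windows (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). A further 21.9% lay in introns, 20.3% between genes and 5.87% in exons. Peaks at TSSs had a median width of 1892 bp and a median fold enrichment of 26.2, and the 14660 distal peaks had 663 bp and 4.55. The share at TSSs was 83.6% among replicated peaks at or above the median fold enrichment.

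TSS peaks marked 14690 of 21911 protein-coding genes (67.04%, 95% interval 66.4 to 67.7), 14836 in the list of replicate 1 and 14790 in that of replicate 2. Genes with a CpG-rich TSS carried a TSS peak in 98.6% of cases (11343 of 11507) and those with a CpG-poor TSS in 32.2% (3347 of 10404); the −log10 p of a one-sided Fisher's exact test was 2821. X-linked genes carried one in 51.9% of cases (492 of 948) and autosomal genes in 68.3% (14194 of 20780; Fisher's exact test, two-sided p = 1.275e-24).

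The next comparison was which genes of regional identity, cell type and other tissues carried the mark. All 28 pallial factors, among them Foxg1, a factor of telencephalic identity, Emx2 and Nr2f1, had a TSS peak. So did all 22 subpallial factors, which include Dlx6, Six3 and Meis2, all 22 diencephalic, eye-field and hem factors, which include Lhx5 and Barhl2, all 24 neural progenitor genes, all 31 neuronal genes, all 26 signalling genes and all 26 housekeeping genes. Of the 32 factors of the midbrain, hindbrain and spinal cord 30 had one, and Evx2 and Phox2b did not. Each of these 8 lists had more TSS peaks than other genes; the adjusted p of Fisher's exact test, two-sided, ran from 4.317e-05 for neuronal genes to 9.658e-04 for the midbrain, hindbrain and spinal cord factors. Matched on CpG at the 5′ end, 3 of the 8 calls held, those of the pallial factors (adjusted p = 0.00732), the diencephalic, eye-field and hem factors (0.0491) and the neuronal genes (1e-04; permutation test, two-sided). A gene marked at another TSS, such as L1cam, was matched by its CpG-poor 5′ end (observed over expected CpG 0.0626). How far the calls that held depend on such genes was not tested. The subpallial, neural progenitor, signalling and housekeeping lists already stood at 100%, the highest share possible. Their matched lists had 93.5%, 90.4%, 89.0% and 88.9%, so the loss of these calls cannot show that CpG accounts for them. All TSS peaks of Foxg1, Neurod1, Bcl11a, Six6, Hes5, Ina, Tbp, Ubc, Sdha and Snrpd3 also covered a TSS of another protein-coding gene, and the 8 lists stayed called with such peaks left out; of these genes all but Foxg1 and Bcl11a were named after their values were seen. The call for midbrain, hindbrain and spinal cord factors was also lost at the stricter fold enrichment (adjusted p = 0.902) and with the 5′ end alone (0.0650; Fisher's exact test).

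Of the 20 lists 5 had fewer TSS peaks than other genes. Of 19 microglial genes 2 had a TSS peak, Hexb and Tmem119, and Csf1r, C1qa and Aif1 had none. Of 18 erythroid genes 5 had one, Klf1 (fold enrichment 31.4), Epor (27.3), Gypa (26.7), Nfe2 (26.9) and Ank1 (50.1), and the globin gene Hba-a1, Gata1 and Alas2 had none. Of 36 differentiation genes of other organs 11 had one, and Alb, the serum albumin gene, had none. Of 20 germline genes 6 had one, and Ddx4 and Acrv1 had none. Of 1418 chemosensory receptor genes 4 had one, Vmn1r4, Olfr94, Olfr1033 and Olfr658. The TSS peaks of Vmn1r4 and of the marked germline genes Gdf9 and Zpbp and the other-organ gene Sftpc also covered a TSS of another protein-coding gene. Tmem119, Gypa, Nfe2, Zpbp and the 3 olfactory receptor genes were named after their values were seen. The adjusted p of Fisher's exact test was 5.122e-06 for microglial, 0.00125 for erythroid, 4.317e-05 for other-organ and 0.00170 for germline genes, and the −log10 p of a one-sided test was 715 for chemosensory receptor genes. Matched on CpG at the 5′ end, the erythroid and other-organ genes no longer differed from other genes (permutation test, adjusted p = 1 and 0.828).

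For 7 lists the share with a TSS peak was not called different. These were, by Fisher's exact test, 21 of 39 Hox genes (adjusted p = 0.118), 28 of 34 mesodermal factors (0.0959), 13 of 20 endodermal factors (0.816), 10 of 17 mature glial genes (0.564), 15 of 20 endothelial and mural genes (0.705), 15 of 20 meningeal and mesenchymal genes (0.705) and 9 of 14 choroid plexus and ciliated genes (0.816). Hoxd13 had a TSS peak and Hoxa2, Hoxa9 and Hoxa11 did not. Nkx2-5, a heart factor, and Hnf4a, a liver factor, had none. The share of Hox genes was below that of other genes with a TSS window of 250 bp (Fisher's exact test, adjusted p = 0.0153), at the stricter fold enrichment (6.765e-08) and matched on CpG at the 5′ end (permutation test, 6.667e-05). In the pooled list and in that of replicate 2, 25 of the 39 had a TSS peak. Hox genes lie close together, and keeping 1 per 100 kb would leave 6 of 39. The tests here and below treat them as separate genes, so their p-values may be too small. The mesodermal factors were called higher by Fisher's exact test in the pooled list (adjusted p = 0.00382), without replicate 1 (0.0389), without replicate 2 (0.0133), with a TSS window of 2.5 kb (0.0148) and with TSS peaks shared with another gene left out (0.00461).

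**Figure D1:**
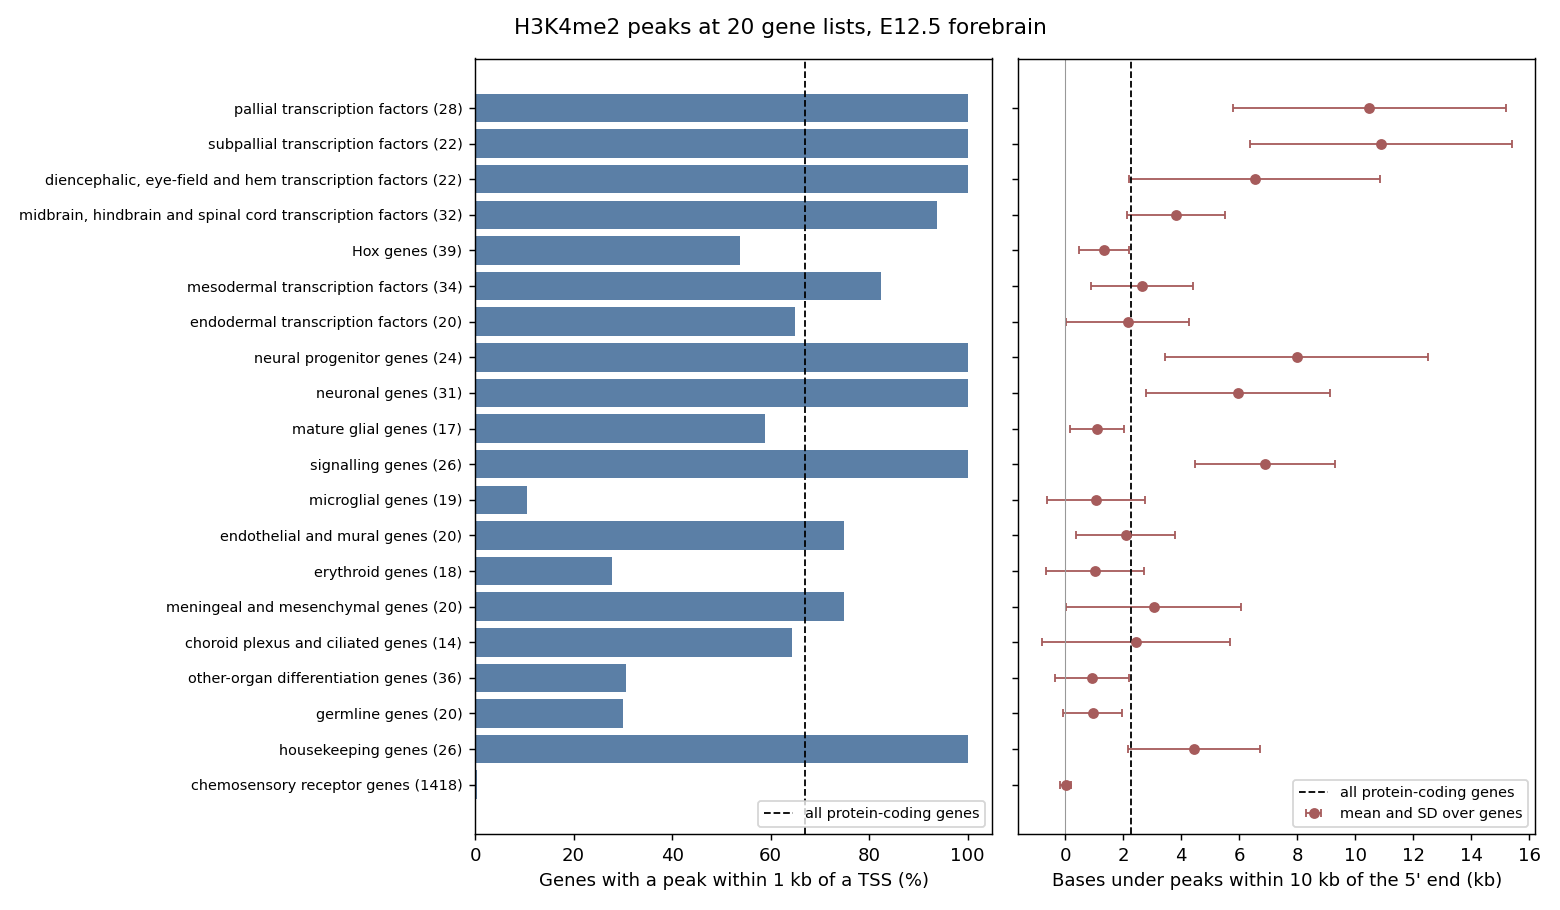
Left, share of the genes of each of 20 lists with a peak within 1 kb of a TSS, in percent, with the number of genes in brackets; right, mean ± SD over genes of the bases under replicated peaks within 10 kb of the 5′ end, in kb. Dashed lines mark all protein-coding genes (67.04% and 2.28 kb); the pallial and subpallial factors lie at 100% and at 10.5 and 10.9 kb.

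The width of the mark around promoters separated the lists further. Within 10 kb of the 5′ end, peaks covered 10.5 ± 4.71 kb at the 28 pallial factors and 10.9 ± 4.51 kb at the 22 subpallial factors (mean ± SD over genes), against 2.27 kb at other genes. Foxg1 had 17.8 kb (16.9 ± 0.356 in the lists of both replicates, n = 2), Emx2 17.2 kb (16.4 ± 0.180), Meis2 20.0 kb (19.7 ± 0.347) and Dlx6 18.2 kb (16.9 ± 1.23). Coverage was 7.98 kb at neural progenitor genes, with 19.4 kb at Sox2, 6.89 kb at signalling genes, with 12.4 kb at Axin2, and 6.54 kb at diencephalic, eye-field and hem factors, with 16.4 kb at Lhx5. It was 5.97 kb at neuronal genes, with 14.2 kb at Slc32a1, the vesicular GABA transporter gene, 4.44 kb at housekeeping genes and 3.83 kb at midbrain, hindbrain and spinal cord factors. These 8 lists were above random lists (permutation test, two-sided, adjusted p = 2.857e-05 for 6 of them, 5e-05 for housekeeping genes and 7.778e-04 for midbrain, hindbrain and spinal cord factors).

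Coverage was below that of random lists for 7 lists (permutation test, two-sided), at 1.34 kb for Hox genes (adjusted p = 0.0186), 1.10 kb for mature glial genes (0.0442), 1.06 kb for microglial genes (0.0292), 1.03 kb for erythroid genes (0.0292), 0.947 kb for germline genes (0.0177), 0.923 kb for other-organ genes (0.00164) and 0.0194 kb for chemosensory receptor genes (2.857e-05). The other 5 lists lay between 2.09 and 3.06 kb and were not called. By the same permutation test the call for mature glial genes was lost in the pooled list (adjusted p = 0.0556), without replicate 1 (0.0657) and without replicate 2 (0.0533). With a window of 25 kb the calls for Hox (0.378), mature glial (0.325), microglial (0.325), erythroid (0.117) and germline genes (0.0756) were lost, and matched on CpG at the 5′ end those for mature glial (0.341), microglial (0.929), erythroid (0.929) and other-organ genes (0.856; permutation tests). The meningeal and mesenchymal genes were then called higher (permutation test, adjusted p = 0.0419). The higher call for midbrain, hindbrain and spinal cord factors was lost at the stricter fold enrichment (permutation test, adjusted p = 0.526) and with a window of 2.5 kb (0.441). Matched on the number of CpG sites within 10 kb they lay at -0.719 kb (list minus matched lists; permutation test, adjusted p = 0.119), the erythroid call was lost (0.0919), and mesodermal (0.00352) and endodermal factors (0.00552) were called lower. In finer bins of CpG number the midbrain, hindbrain and spinal cord factors lay further below, at -1.84 kb, which was not tested against matched lists. Coverage is counted from the outermost annotated 5′ end, which lies away from the marked TSS at L1cam (0 kb), Notch1 (0.879 kb) and Nfib (2.07 kb), and neighbouring genes share windows, as at Cd68, which had 6.52 kb covered and no TSS peak.

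The 72 forebrain factors and the 32 factors of the midbrain, hindbrain and spinal cord were compared directly. Mean coverage was 9.40 ± 4.87 kb at the forebrain factors and 3.83 ± 1.68 kb at the others, a difference of 5.57 kb (95% bootstrap interval 4.31 to 6.82; permutation test, two-sided p = 1e-05, the smallest that it can give). Olig3 with 6.40 kb, Pax3 with 7.45 kb and Gata2 with 6.48 kb were the most covered of the others, and En1, a midbrain and hindbrain factor, had 3.35 kb. Factors were placed in the lists beforehand, and whether those of the second set are also expressed in parts of the dissected forebrain was not measured. TSS peaks were present at 100% of the forebrain factors and 93.8% of the others, which was not called (Fisher's exact test, two-sided p = 0.0926). That difference was called by Fisher's exact test with a TSS window of 250 bp (p = 0.0272), with the 5′ end alone (0.00997) and at the stricter fold enrichment (0.00271). It was absent with a TSS window of 2.5 kb, where all factors of both sets had a TSS peak (Fisher's exact test, p = 1), and smaller without replicate 2 (3.125 percentage points, p = 0.308).

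**Figure D2:**
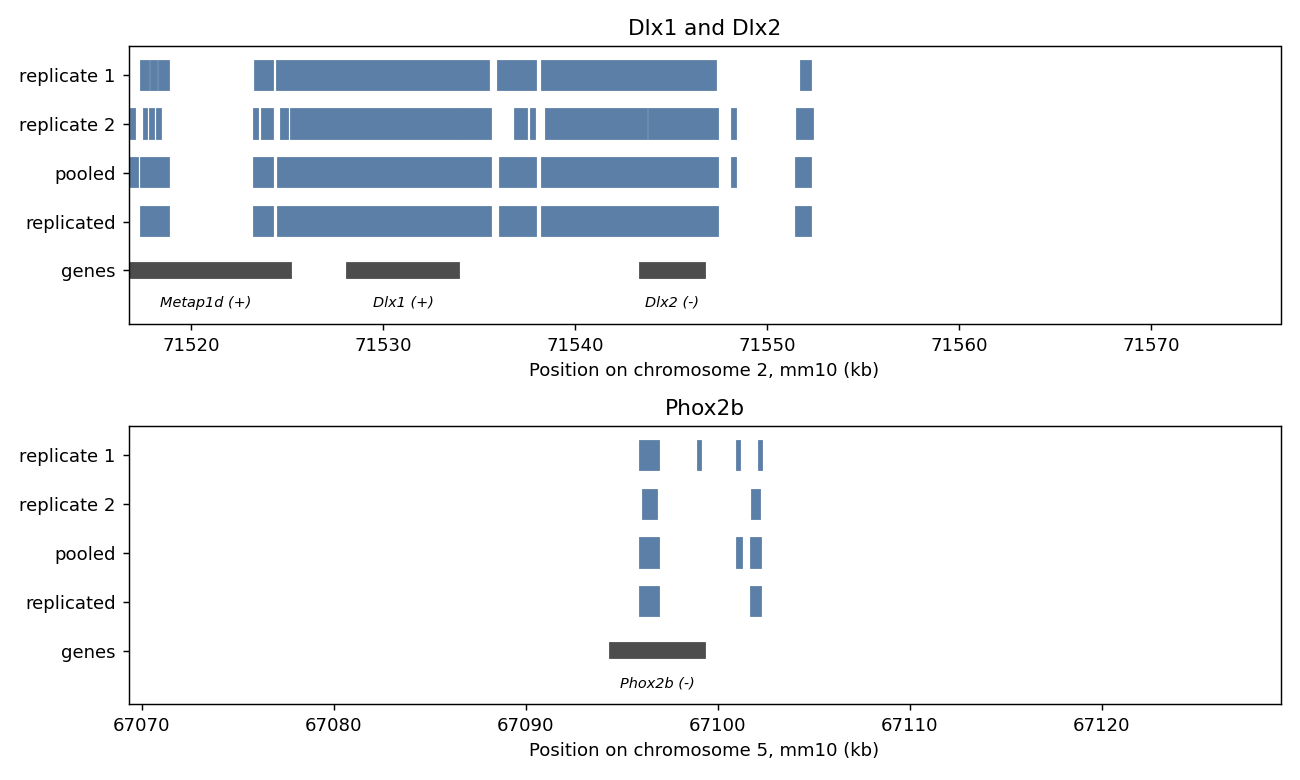
Peaks of the 4 lists (blue) and protein-coding genes (grey, strand in brackets) around Dlx2 on chromosome 2 and Phox2b on chromosome 5, by position in kb on mm10. Replicated peaks cover Dlx1 and Dlx2 nearly end to end, from 71523285 to 71547478 on chromosome 2, while Phox2b has no replicated peak within 1 kb of its TSS.

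The next comparison was which genes had the widest domains over a TSS. Nr2f1, a nuclear receptor gene of cortical patterning, had a merged domain of 41.2 kb, but 20.7 ± 5.74 kb in the lists of both replicates (n = 2). Zic1 and Zic4 shared a domain of 39.2 kb (31.7 ± 10.3), Pou3f3 had 32.1 kb (32.1 ± 0.114), Sox2 32.1 kb (26.5 ± 7.76) and Nr2f2 29.9 kb (30.2 ± 0.442). Lhx2 had 24.6 kb (24.3 ± 0.153), Pax6 24.1 kb (23.9 ± 0.0679) and Ptch1, the receptor gene of the hedgehog pathway, 22.5 kb (22.4 ± 0.0693). Dlx1 and Dlx2 shared 24.2 kb in the replicated list, but had 18.2 ± 8.26 kb and 16.5 ± 10.6 kb in the lists of both replicates. The median over marked genes was 2.51 kb. Of the 20 genes with the widest domains 9 were in the forebrain factor lists, and among the 200 widest were 33 of the 72 forebrain factors and 0 of the 32 midbrain, hindbrain and spinal cord factors; the cutoff of 200 was chosen after seeing the data (Fisher's exact test for the forebrain factors, two-sided p = 7.963e-49). Widths depend on how peaks are joined: without joining, the domain was 9.04 kb at Nr2f1, 13.4 kb at Zic1 and Zic4, 19.9 kb at Pou3f3, 4.28 kb at Sox2, 8.79 kb at Nr2f2, 11.1 kb at Dlx1, 9.17 kb at Dlx2, 17.8 kb at Pax6 and 8.63 kb at Ptch1, and unchanged at Lhx2.

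**Figure D3:**
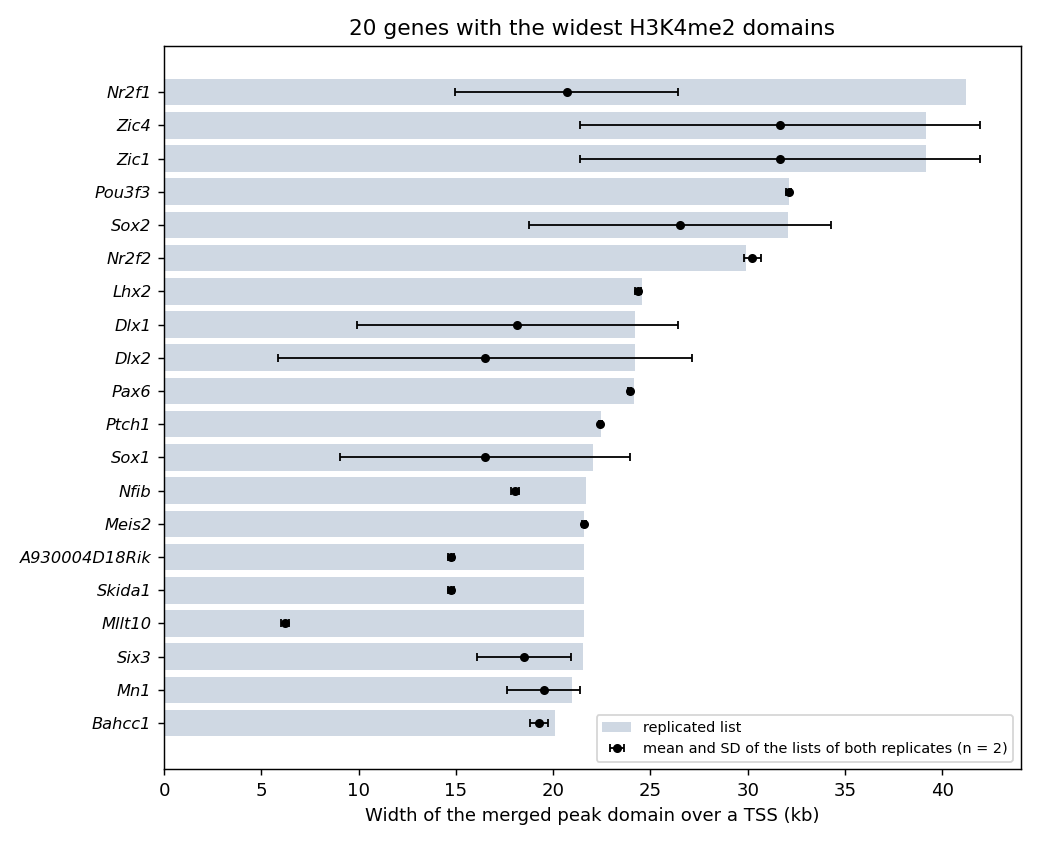
Width in kb of the merged peak domain over a TSS for the 20 protein-coding genes with the widest domains: bars, replicated list; points and lines, mean ± SD of the lists of both replicates (n = 2). Pou3f3 (32.1 kb) and Lhx2 (24.6 kb) have nearly the same width in both replicates, while Nr2f1 falls from 41.2 kb to a mean of 20.7 kb.

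Distal peaks were compared between the same lists. Within 100 kb of the 5′ end there were 6 ± 3.39 distal peaks at subpallial factors and 5.43 ± 4.53 at pallial factors (mean ± SD over genes), against 1.45 at other genes. In the lists of single replicates these means were 8.77 to 9.73 at subpallial and 7.96 to 8.79 at pallial factors, against 2.38 to 2.48 at other genes, and in the pooled list 9.36 and 8.64 against 2.74. In the replicated list the mean was 4.83 at neural progenitor genes, 4.44 at midbrain, hindbrain and spinal cord factors, 4.35 at signalling genes, 4.09 at diencephalic, eye-field and hem factors, 3.00 at microglial genes, 2.42 at neuronal genes and 2.35 at mesodermal factors. These 9 lists were above random lists (permutation test, two-sided, adjusted p from 2.857e-05 to 0.0272), and the chemosensory receptor genes were below them with 0.200 (2.857e-05). The remaining 10 lists lay between 1.39 and 2.14 and were not called. The microglial genes C1qa and C1qb had no TSS peak and 8 and 9 distal peaks in overlapping windows, which count the same peaks more than once; by nearest 5′ end they had 2 and 3. With 1 gene kept per locus, an alternative chosen after seeing the data, the mean of microglial genes was 2.41 and they were no longer called (permutation test, two-sided, adjusted p = 0.105), and the other calls held. By the same permutation test the call for mesodermal factors was lost in the pooled list (adjusted p = 0.144) and without replicate 1 (0.0842), that for neuronal genes at the stricter fold enrichment (0.529) and with distal peaks over 5 kb from a TSS (0.154), and those for microglial genes (0.196) and diencephalic, eye-field and hem factors (0.0957) at the stricter fold enrichment.

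By nearest 5′ end, Bcl11b, a zinc finger factor of subcortical projection neurons, had 19 distal peaks within 100 kb, Gse1 18, Bcor 17, Ncor2 16, and Bcl11a, Pbx1 and Gm11733 had 14 each. Such numbers depend on the list. All distal peaks within 100 kb numbered 19 at Bcl11b, 21 at Gse1 and 16 at Bcl11a in the replicated list. They numbered 33, 31 and 20 in the list of replicate 1 and 31, 34 and 19 in that of replicate 2. Forebrain factors had 5.19 distal peaks and midbrain, hindbrain and spinal cord factors 4.44, a difference of 0.757 (95% bootstrap interval -0.747 to 2.18; permutation test, two-sided p = 0.335), which was called without replicate 1 (2.14, p = 0.0462). Pallial and subpallial factors did not differ detectably, with pallial minus subpallial at -0.571 (interval -2.68 to 1.61; permutation test, two-sided p = 0.628). The nearest gene need not be the gene that a distal peak acts on.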

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

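No test was run on the peaks below, and their fold enrichments were listed after the other results had been seen. Peaks were also listed in sequence that the comparisons did not use. The replicated list held 11 peaks on unplaced or unlocalized scaffolds, with fold enrichments from 2.90 to 13.5. They were left out because gene positions were taken from assembled chromosomes, no expected number was available to set the count against, and no explanation was tested.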

How the results depend on the processing

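Alternatives chosen after seeing the data were the replicated peaks overlapped by 50% in both replicates, matching on CpG number, 1 gene per locus for distal peaks and leaving out TSS peaks shared with another gene. The library depth is unknown, which limits what weak peaks can show. Of the main results under their alternatives, 108 stayed the same, 13 values moved, 4 passed the threshold and 5 changed direction. For tests, the same meant an unchanged direction and side of the threshold. Counts of called lists were taken as the same when near the main count, so single lists could gain or lose a call. The rank correlation and the share of pooled peaks in the replicated list were the same when inside the main interval. The causes of the changes were not tested. The rank correlation of fold enrichment was 0.941 with reciprocal overlap and 0.903 at the stricter fold enrichment, and 99.9% of pooled peaks at or above the median were in the replicated list. Genes with a TSS peak made up 63.5% at the stricter fold enrichment, 68.1% in the pooled list, 67.5% to 67.7% when each replicate was left out, 66.1% with a window of 250 bp, 68.2% with 2.5 kb and 63.5% with the 5′ end alone. Matched on CpG at the 5′ end, 3 lists had more TSS peaks and 3 less coverage; with a window of 25 kb 2 lists had less coverage. Forebrain factors exceeded midbrain, hindbrain and spinal cord factors in TSS peaks by 26.0 percentage points at the stricter fold enrichment, 9.38 with 250 bp and 15.97 with the 5′ end alone, by 3.125 to 6.25 when each replicate was left out, and by 0 with 2.5 kb, where all had one. In distal peaks they differed by -0.0243 at the stricter fold enrichment and by 1.65 to 2.14 when each replicate was left out. Pallial minus subpallial distal peaks was 0.0260 at the stricter fold enrichment, 0.506 within 50 kb, 0.458 at over 5 kb and -1.76 to 0.0130 when each replicate was left out.

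Single lists changed direction 32 times, given as list minus comparison. In percentage points with a TSS peak, in the pooled list endodermal factors were at 1.92 and choroid plexus and ciliated genes at 3.35; with shared TSS peaks left out they were at 7.79 and 7.07. When each replicate was left out, endodermal factors were at -2.71 to 2.502, choroid plexus and ciliated genes at -3.43 to 3.93 and mature glial genes at 2.88 to 3.09; mature glial genes were at 8.32 matched on CpG, and meningeal and mesenchymal genes at -3.54 at the stricter fold enrichment. In kb covered, mesodermal factors were at -0.350 at the stricter fold enrichment, -0.308 within 2.5 kb and -1.24 matched on CpG number (permutation test, adjusted p = 0.00352, the only one of the 32 below 0.05). Matched on CpG number, midbrain, hindbrain and spinal cord factors were at -0.719 and choroid plexus and ciliated genes at -0.164; the latter were at -0.537 within 2.5 kb, and erythroid genes at 0.0737 matched on CpG at the 5′ end. In distal peaks, at the stricter fold enrichment Hox genes were at 0.170, erythroid genes at 0.101 and other-organ genes at 0.129. With peaks overlapped by 50%, Hox genes were at 0.114 and erythroid genes at 0.0114; with 1 gene per locus erythroid genes were at 0.233. Within 200 kb, Hox genes were at 1.06, erythroid genes at 0.789 and mature glial genes at -0.399; within 50 kb, endothelial and mural genes were at -0.0107 and other-organ genes at 0.0115; at over 5 kb, choroid plexus and ciliated genes were at -0.00648. Germline genes were at -0.199 in the pooled list and at -0.0855 to 0.216 when each replicate was left out, and other-organ genes then at -0.136 to 0.0711. Of the other list results 508 stayed as they were, 30 lost their call and 10 gained one.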

Other observations

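The tests of CpG number, of CpG-rich TSSs and of other cells in the dissection were set after related results had been seen, and the gene families were chosen after the lists had been examined. The patterns for defensins, interleukins and chemokines, and zinc finger genes were corrected or renamed once after a first look, because they had taken in Def8 and interleukin receptors.

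Of 19 gene families picked by symbol, the Zic factors were the most covered, with 16.1 ± 3.69989 kb (mean ± SD over 5 genes) within 10 kb of the 5′ end, of which Zic4 had 19.2 kb and Zic1 18.5 kb. The LIM homeobox factors had 8.09 kb, with 16.4 kb at Lhx5, the Sox factors 7.54 kb, with 19.4 kb at Sox2, the histone cluster genes 7.32 kb and the POU factors 5.77 kb, with 19.9 kb at Pou3f3. Each was above random lists of the same size (permutation test, two-sided, adjusted p = 1.727e-05) and above lists matched on the number of CpG sites within 10 kb (adjusted p at most 2.418e-04). Members that lie close together, as Zic1 and Zic4 do, share windows and count the same peaks more than once. The random lists do not allow for this, and its effect on these p-values was not tested. The forkhead factors, with 4.21 kb, did not differ from lists matched on CpG number (expected 4.09 kb; permutation test, adjusted p = 0.822). The ephrins and Eph receptors, guidance molecules of growing axons, had a TSS peak at 22 of 22 genes and 5.80 kb covered, with 12.9 kb at Epha4. All 16 ionotropic glutamate receptor subunit genes had a TSS peak (permutation test, adjusted p = 0.00778), and 14 of 19 GABA-A receptor subunit genes did (0.668).

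The clustered protocadherin genes, cell-adhesion genes with many alternative promoters, had a TSS peak at 17 of 56 members and 1.15 kb covered, below the 3.33 kb expected from their CpG number (permutation test, adjusted p = 2.714e-05). Pcdhgc4 and Pcdhgc3 stood out among them with 12.7 and 10.2 kb. The keratin genes had a TSS peak at 8 of 49 members, the cytochrome P450 genes at 25 of 99 and the defensins at 0 of 64. Proteasome subunit genes had one at 38 of 39 members and ribosomal protein genes at 88 of 92. Histone cluster genes had 6.37 distal peaks on average. For these and the clustered protocadherin genes, the effect of windows shared between neighbouring members was not tested.

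Wider coverage at forebrain factors than at midbrain, hindbrain and spinal cord factors was weighed against technical sources. With the mean of genes of similar CpG number subtracted, forebrain factors lay at 3.87 kb and the others at -1.84 kb. The difference was then 5.71 kb (permutation test, two-sided p = 1e-05), so CpG number does not account for it. With peaks over the TSSs of other protein-coding genes removed it was 5.15 kb (permutation test, p = 2e-05), and around the most covered TSS of each gene it was 6.45 kb (p = 1e-05), which argues against neighbouring promoters and against the choice of 5′ end. A remaining hypothesis is that wide H3K4me2 domains may mark the factors active in the dissected tissue. The design holds 1 tissue, so this was not tested.

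TSS peaks at factors of other regions and germ layers were set against lists matched on CpG at the 5′ end, which gave no common answer. The Hox genes lay at -35.1 percentage points (53.8% against 89.0%; permutation test, two-sided p = 1e-05), which leaves open why 21 of them were marked, while the midbrain, hindbrain and spinal cord factors lay at 6.84 (p = 0.125), the mesodermal factors at 1.65 (p = 0.787) and the endodermal factors at -9.36 (p = 0.262), too few genes to decide. Hox genes lie close together, which the matched lists do not allow for. Muscle and red blood cells in the dissection stay open: 5 of 17 muscle structural and globin genes had a TSS peak, 4.87 percentage points above matched lists (permutation test, two-sided p = 0.748), all 5 of them muscle genes. Because that test took both cell types together, it cannot decide for either alone. Of 18 erythroid genes, Klf1, Epor, Gypa, Nfe2 and Ank1 had TSS peaks with fold enrichments of 26.7 to 50.1. The other 13, among them Hba-a1, Gata1 and Alas2, had none. The marked share of the erythroid list, 27.8%, was near the 28.7% of lists matched on CpG at the 5′ end. Meningeal, mesenchymal, endothelial and mural cells stay open too, since 30 of 40 of their genes had a TSS peak (75%), 9.92 percentage points above matched lists (permutation test, two-sided p = 0.135). Biological explanations for marked but narrow promoters of factors of other lineages were not tested.

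Fewer TSS peaks on X-linked genes were the third pattern. X-linked genes lay -7.86 percentage points from genes matched on CpG at the 5′ end (51.9% against 59.8%; permutation test, two-sided p = 1e-05), so CpG at the 5′ end does not account for all of it. CpG at the other TSSs of a gene, where a TSS peak could also lie, was not matched. Among genes whose symbol stem has under 5 X-linked members the X share was 74.2% of 550 genes and the autosomal share 76.2% of 16426, a difference of -1.996 percentage points (Fisher's exact test, two-sided p = 0.286). A symbol stem is a naming prefix that unrelated genes can share, and leaving such genes out also raised the autosomal share from 68.3%. The comparison therefore cannot single out multicopy families as the source of the difference, and a smaller difference cannot be ruled out. No biological explanation was tested.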
